A study of Mus musculus with 57 samples.

How the data were processed

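Messenger RNA was measured in liver, lung and blood of female C57BL/6 mice, aged 8 weeks, on 57 Illumina MouseWG-6 v2 BeadChip arrays, 19 per tissue. Per the labels, the mice received 50 µl Todd-Hewitt broth alone by the intratracheal route (sham) or broth with 100000 CFU of Streptococcus pneumoniae per mouse. Serotype 2 (strain D39) stood for invasive disease and serotype 19 (strain EF3030) for pneumonia that stays in the lobe. Tissue was taken 6 or 24 h later. Blood RNA came from stabilising tubes and was cleared of globin transcripts before labelling. All sham samples were marked 6 h, so that none matched the 24 h groups in time. The labels do not say whether each array came from a separate mouse, and p-values measure the spread between these samples.

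The deposited signal table holds linear signal intensity for 45281 probes on every array, with no background subtraction or between-array normalization seen in its values. Beside each signal column, per the file headers, stands a detection p-value for each probe, which compares the probe with negative control beads. BeadStudio 3.23 is listed per the submitters' processing notes, which do not state its role. The deposited series matrix holds a log2 scale made by the authors with a method that is only partly known. Within every array its ranks matched those of the signal with a rank correlation of 1. Its array medians ran from 6.81 to 6.88 in liver, 5.99 to 6.11 in lung and 4.24 to 4.67 in blood, so the scale was set differently per tissue. That matrix served as an alternative to the values normalized from the signal.

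The median signal per array was 102.7 to 145.1 in liver, 119.3 to 153.9 in lung and 97.6 to 205 in blood. The percent of probes detected at a detection p under 0.05 was 37.1 to 43.5 in liver, 48.0 to 53.9 in lung and 29.0 to 42.9 in blood. No pair of arrays held identical values. Pearson correlations between arrays of a tissue were 0.951 to 0.993 in liver, 0.923 to 0.991 in lung and 0.921 to 0.986 in blood. The number of arrays limits the precision.

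Within each tissue, limma's normexp correction took the negative control mean and spread from the detection p-values and added an offset of 16. The corrected signal was quantile normalized and put on a log2 scale. Probes detected at p under 0.05 on at least 3 arrays of the tissue were kept, which left 21821 probes in liver, 26957 in lung and 21657 in blood. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. Each named gene was represented by the probe with the highest mean, which gave 11588 genes in liver, 13399 in lung and 11181 in blood. Where a gene was not detected on any array of its dimmer group, the fold change is given as a lower bound, computed with that group's values raised to the detection floor of each array.

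Groups were compared with limma 3.58.1 in R 4.3.3. A single fit per tissue held a mean for each of the 5 groups, and 8 differences per tissue were taken, together with the serotype by time interaction. The 4 infected groups were each set against sham, the serotypes against each other at each time, and 24 h against 6 h within each serotype. P-values were adjusted by the Benjamini-Hochberg method over all genes of a tissue and comparison, with a threshold of 0.05. The tests were two-sided. Before the data were examined, 31 lists of pathway members and cell type markers were written down, as were the comparisons, the settings and the choice of genes to name. Lists with at least 5 measured members were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, and again with the correlation estimated from the data. List p-values were adjusted over the lists tested in that comparison. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone.

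Named genes followed a rule. For each infected group against sham these were the 5 largest rises and the 5 largest falls among genes past the threshold whose infected arrays all lay above or all below every sham array. The other comparisons took 3 rises and 3 falls in the same way. Each described list gave up to 4 members with the smallest adjusted p, or, where no member passed, the 2 members with the highest mean signal as values only. In liver, every member of the cholesterol biosynthesis list could be named. Predicted genes without a proper name were passed over, and not every gene the rule allows is named, nor every list that passed described.

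To compare the tissues, all 57 arrays were normalized together, which left 14878 genes, and the change from sham in liver was set against that in lung or blood in a single limma fit of all 15 groups. On simulated data with 200 changed genes in the comparison of serotype 2 at 24 h with sham, the liver procedure recovered 75% of genes changed by 1 on the log2 scale and 98% of those changed by 2 over 11588 genes. In lung these were 74% and 96% (13399 genes) and in blood 63% and 97% (11181 genes). Of the simulated calls 6.49%, 6.08% and 5.33% were false. Real calls may differ.

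The alternatives tried were an offset of 50, the deposited log2 matrix, median scaling in place of quantile normalization, normalization of all 57 arrays together, no detection filter, a stricter filter (detection p under 0.01 on every array of a group), every probe in place of 1 per gene, a variance trend with robust estimation, the replicate number as a block, a fit of only the 2 groups compared, a required doubling or halving, and leaving out each array in turn. Other alternatives were added after the data were seen: leaving out a pair of lung arrays with high muscle transcripts, and fits with the muscle list mean (lung) or the detected share (blood) as a covariate. The array leaving-out alternatives for liver sham replicate 2 and blood sham replicate 3 were singled out at that stage too. Array position was not used as a block, since no slide was given.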

Results

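Gene expression was measured in the liver, lung and blood of mice 6 and 24 h after pneumococci were placed in the airway. Each tissue had 3 sham arrays and 4 arrays for serotype 2 (S2, invasive) and for serotype 19 (S19, lobar) at each time, 19 arrays per tissue and 57 in all. Arrays are named by group and replicate number. Changes are log2 fold changes unless a fold is named, values after ± are standard errors of the limma fit, and adjusted p-values come from limma for genes and from camera for gene lists. A comparison with sham set 4 infected against 3 sham arrays, and the others set 4 against 4. The sham samples were marked 6 h, so a 24 h change from sham holds both infection and time.

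**Figure D1:**
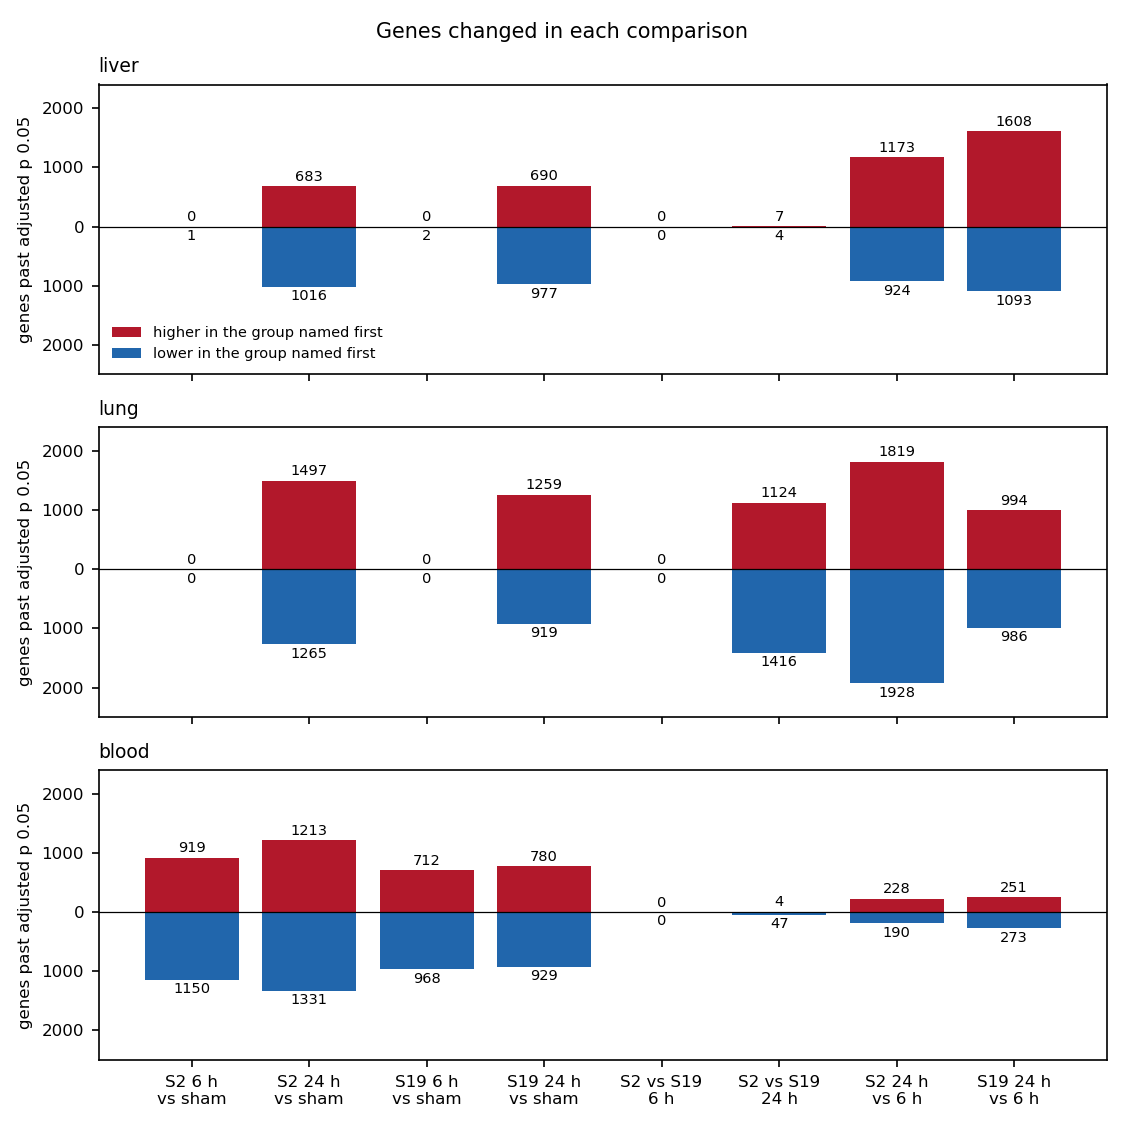
Number of genes past an adjusted p of 0.05 in each comparison (horizontal axis) for liver, lung and blood, with bars above 0 for genes higher in the first group and below 0 for genes lower. In liver and lung the bars at 6 h against sham hold at most 2 genes, and in blood they hold 2069 genes for serotype 2 and 1680 for serotype 19.

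The liver comparisons asked how an organ remote from the infected lung responded, with cholesterol synthesis as the process named by the study. Against sham, livers 24 h after serotype 2 carried more transcripts of sterol synthesis, acute phase proteins, interferon-induced genes and neutrophil granule proteins. Prtn3, which encodes the neutrophil protease proteinase 3, rose by 5.39 ± 0.82 and was detected on 2 of the 3 sham arrays. Lcn2, which encodes an iron-sequestering acute phase protein, rose by 3.25 ± 0.72, and Mvd, an enzyme of the mevalonate pathway, rose by 2.94 ± 0.42. Cyp2b10, a drug-metabolising cytochrome P450, fell by 4.58 ± 0.55 (another probe gave -1.61), Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 3.11 ± 0.74, and the lipid droplet protein gene Cidec fell by 3.18 ± 0.66 and was detected on 2 of 4 infected arrays. Tmprss7, a membrane serine protease, was at least 9.30-fold lower and was not detected after infection. Limma called 1699 of 11588 genes changed, 683 higher and 1016 lower, of which 207 at least doubled and 224 at least halved. The count was 892 without sham replicate 2, 677 in a fit of only the 2 groups, 2619 over all probes and 1072 under median scaling, where 61.5% of the called genes were higher in place of 40.2%.

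Of the 16 measured cholesterol biosynthesis genes, 8 rose and none fell after serotype 2 at 24 h (10 adjusted over the list alone), with a median change of 0.90 and an adjusted p = 1.58e-07 (adjusted p = 0.208 with an estimated correlation). Besides Mvd, the sterol methyl oxidase Msmo1 rose by 1.85 ± 0.23, squalene epoxidase Sqle by 1.81 ± 0.29 and the sterol dehydrogenase Nsdhl by 2.15 ± 0.45. Nsdhl rose by 1.34 without sham replicate 2, and other probes gave 0.97, 2.64 and 2.78. Among 6 genes of sterol uptake and feedback 2 rose (3 adjusted over the list alone), the transcription factor gene Srebf2 by 1.40 ± 0.19 and Insig1, which holds that factor in the endoplasmic reticulum, by 1.58 ± 0.33 (list median 0.51, adjusted p = 0.00187, adjusted p = 0.208 with an estimated correlation). Acute phase genes rose in 14 of 31 members (16 adjusted over the list alone), with a list median of 0.46 and an adjusted p = 1.43e-07 (adjusted p = 0.208 with an estimated correlation). Serum amyloid P (Apcs) rose by 2.08 ± 0.30. Complement and coagulation genes rose in 5 of 29 members (6 adjusted over the list alone). Mbl1, a mannose-binding lectin, rose by 1.06 ± 0.14 (list median 0.23, adjusted p = 0.000314, adjusted p = 0.181 with an estimated correlation). Of 35 interferon-stimulated genes 16 rose (26 adjusted over the list alone). The GTPase Irgm2 rose by 2.25 ± 0.41 (list median 0.81, adjusted p = 2.58e-12, adjusted p = 0.208 with an estimated correlation). Cytokine and adhesion genes rose in 6 of 23 members (6 adjusted over the list alone). Icam1 rose by 1.56 ± 0.35 (list median 0.41, adjusted p = 0.00058, adjusted p = 0.284 with an estimated correlation). Neutrophil granule genes rose in 3 of 5 members (4 adjusted over the list alone, list median 1.22, adjusted p = 0.00058, adjusted p = 0.179 with an estimated correlation). With no detection filter the granule median was 0.11 and the cytokine median 0.12.

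Genes of gluconeogenesis and amino acid breakdown fell in 6 of 14 members after serotype 2 at 24 h, and adjusted over the list alone 9 were lower and 1 higher. The urea cycle enzyme Ass1 fell by 0.83 ± 0.15 (list median -0.53, adjusted p = 0.00104, adjusted p = 0.212 with an estimated correlation). Of 14 clock genes 6 fell and 2 rose (6 and 2 adjusted over the list alone). Ciart fell by 2.82 ± 0.39 and Per2 fell by 1.41 ± 0.29 (list median -0.38, adjusted p = 0.0131, adjusted p = 0.208 with an estimated correlation). The clock median was -0.59 without sham replicate 1, -0.60 without sham replicate 2 and -0.41 with adjusted p = 0.0556 without sham replicate 3. Endoplasmic reticulum stress and chaperone genes rose in 5 of 22 members (6 adjusted over the list alone). Chac1, a glutathione-degrading enzyme induced by stress, rose by 2.25 ± 0.36 (list median 0.47, adjusted p = 1.15e-05, adjusted p = 0.208 with an estimated correlation). That median was 0.29 without S2 24 h replicate 4. In fatty acid oxidation and ketogenesis 4 of 19 genes fell and 1 rose (5 and 2 adjusted over the list alone). The list as a whole did not pass (median -0.12, adjusted p = 0.486), and its median was 0.0088 without sham replicate 1.

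Livers 24 h after serotype 19 asked the same question for infection that stays in the lung. Mvd rose by 4.16 ± 0.42, Pnpla3, a lipid droplet phospholipase-like protein gene, rose by 2.98 ± 0.55 and was detected on 2 of 3 sham arrays, and the transcription factor gene Nfe2 was at least 13.5-fold higher, with no detection in sham. Cyp2b10 fell by 4.67 ± 0.55 (another probe gave -1.67) and Eif4ebp3, which encodes a translation repressor, fell by 4.11 ± 0.48. Cidec was at least 10.1-fold lower. Cdkn1a, which encodes a cell cycle inhibitor, fell by 3.71 ± 0.99 (another probe gave -1.17, adjusted p = 0.421), with adjusted p = 0.0595 without sham replicate 1 and 0.0584 without sham replicate 2. Limma called 1667 genes, 690 higher and 977 lower, of which 174 at least doubled and 203 at least halved. Without sham replicate 2 the count was 903, and under median scaling 79.2% of the called genes were higher in place of 41.4%.

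After serotype 19 at 24 h, 11 of the 16 cholesterol biosynthesis genes rose and none fell (13 adjusted over the list alone), with a median change of 1.38 and an adjusted p = 2.63e-10 (adjusted p = 0.140 with an estimated correlation). Msmo1 rose by 2.04 ± 0.23 and Sqle by 1.81 ± 0.29. Another probe for Lss, a member that passed, gave -0.05. Sterol uptake and feedback genes rose in 5 of 6 members (6 adjusted over the list alone). Srebf2 rose by 1.24 ± 0.19 and Insig1 by 1.80 ± 0.33 (list median 0.87, adjusted p = 3.19e-05, adjusted p = 0.140 with an estimated correlation). Amino acid and gluconeogenesis genes fell in 5 of 14 members (6 adjusted over the list alone). The tryptophan-degrading Tdo2 fell by 1.82 ± 0.36 (list median -0.45, adjusted p = 0.00556, adjusted p = 0.691 with an estimated correlation). Interferon-stimulated genes rose in 4 of 35 members (1 adjusted over the list alone). Their list median was 0.51 with an adjusted p = 3.19e-05 (adjusted p = 0.773 with an estimated correlation). Neutrophil granule genes rose in 2 of 5 members (3 adjusted over the list alone). The granule transcription factor gene Cebpe rose by 1.26 ± 0.23 (list median 1.26, adjusted p = 0.00556, adjusted p = 0.140 with an estimated correlation), a call that ended with no detection filter (median 0.066, adjusted p = 0.162). The acute phase list did not pass (5 of 31 higher and 3 lower, 7 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.270), with medians of -0.015 without sham replicate 2 and -0.016 in the deposited matrix. It passed without S19 24 h replicate 3 (median 0.11, adjusted p = 0.0127). The clock list did not pass (median -0.23, adjusted p = 0.233), with 4 of 14 members lower (4 adjusted over the list alone), including Ciart by -2.81 ± 0.39, and its median was 0.0012 under median scaling. Fatty acid oxidation did not pass (4 of 19 lower and 1 higher, 6 and 2 adjusted over the list alone, median -0.11, adjusted p = 0.198). Under median scaling its median was 0.034 with adjusted p = 0.0390.

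**Figure D2:**
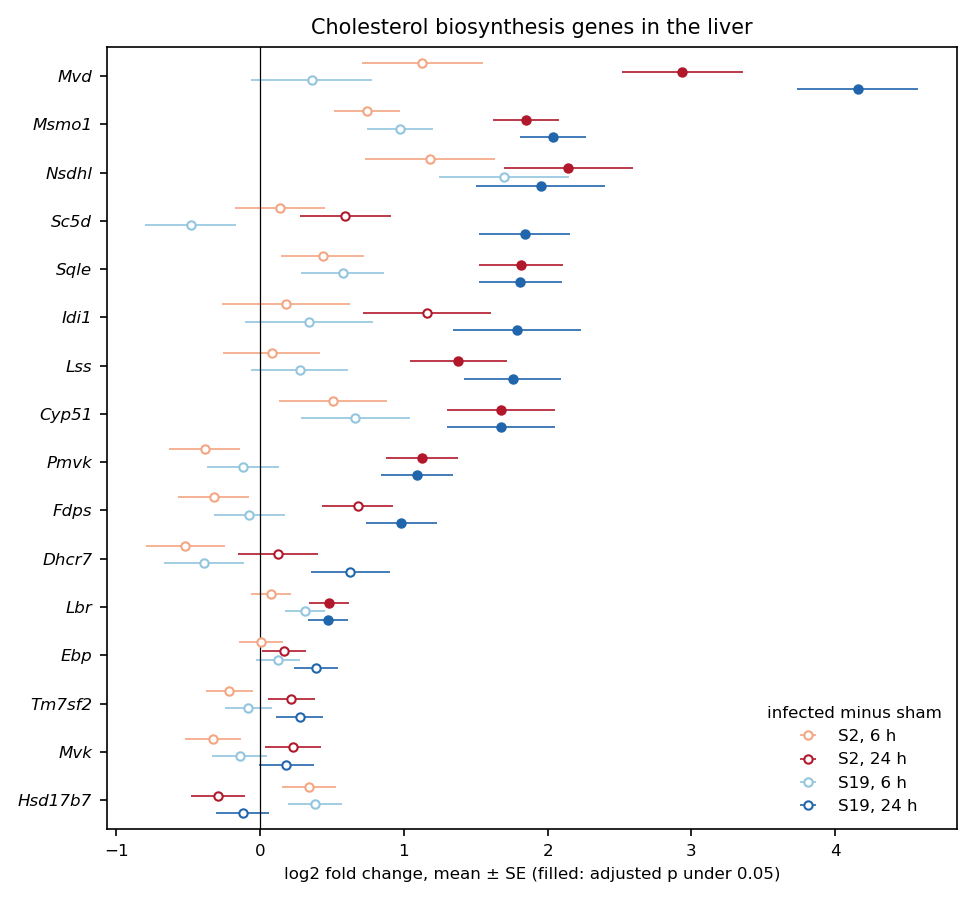
Log2 fold change from sham with its standard error (horizontal axis) for the 16 measured cholesterol biosynthesis genes in liver (vertical axis), for both serotypes at 6 and 24 h. Filled points passed an adjusted p of 0.05, which 8 genes did for serotype 2 and 11 for serotype 19 at 24 h, and 0 did at 6 h in these fits.

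At 6 h few single liver genes passed against sham. After serotype 2, Rhebl1, a small GTPase gene, was at least 1.80-fold lower and was not detected on infected arrays (log2 -1.20 ± 0.18, adjusted p = 0.0272), and it was the 1 gene called by limma, where 1905 genes had an unadjusted p under 0.05. After serotype 19, Rab11fip4, an endosome recycling gene, fell by 1.48 ± 0.22 (another probe gave -0.26, adjusted p = 0.572) and Brdt, a testis bromodomain gene detected on 1 of 4 infected arrays, fell by 1.11 ± 0.16, and these were the 2 genes called (2233 unadjusted). Rhebl1 had adjusted p = 0.174 without sham replicate 2 and 0.152 without S2 6 h replicate 1. Rab11fip4 and Brdt had adjusted p = 0.176 without sham replicate 2, 0.107 and 0.0833 without sham replicate 3, and 0.115 without S19 6 h replicate 1. The serotype 2 count was 650 without sham replicate 1, 0 without sham replicate 2, 3 without sham replicate 3, and 0, 6, 9 and 7 without S2 6 h replicates 1 to 4. For serotype 19 the count was 1267 without sham replicate 1, 0 without sham replicate 2 or 3, and 0, 10, 213 and 48 without S19 6 h replicates 1 to 4. The other settings gave 0 to 22 genes for serotype 2 and 0 to 82 for serotype 19.

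The cholesterol list did not pass at 6 h after serotype 2 (0 of 16, 0 adjusted over the list alone, median 0.11, adjusted p = 0.0833). Its most abundant members gave -0.32 ± 0.25 (Fdps, another probe 1.33 with adjusted p = 0.316) and 0.0075 ± 0.15 (Ebp). The median was 0.23 (adjusted p = 0.00686) without sham replicate 1, 0.13 (0.0334) without S2 6 h replicate 1 and 0.34 (0.00880) without replicate 3. It was -0.10 without sham replicate 2, -0.025 without S2 6 h replicate 2 and -0.025 without replicate 4. After serotype 19 the list passed with 0 of 16 genes over all genes and 2 adjusted over the list alone (median 0.30, adjusted p = 0.0186, adjusted p = 0.937 with an estimated correlation). That call ended without sham replicate 2 (median 0.055, adjusted p = 0.360), without S19 6 h replicate 4 (0.20, adjusted p = 0.118) and with the replicate number as a block (0.17, adjusted p = 0.148). Fatty acid oxidation and ketogenesis as a list shifted upward at 6 h, by a median of 0.18 for serotype 2 (0 of 19 genes, 0 adjusted over the list alone, adjusted p = 0.000666, adjusted p = 0.518 with an estimated correlation) and 0.36 for serotype 19 (0 of 19, 4 adjusted over the list alone, adjusted p = 1.73e-06, adjusted p = 0.736 with an estimated correlation).

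Set against each other at 24 h, livers after serotype 2 and serotype 19 differed in few genes. Chac1 was higher after serotype 2 by 2.95 ± 0.33 and passed with each array left out. Snx10, an endosome sorting gene, was higher by 1.32 ± 0.22 (another probe 0.63, adjusted p = 0.614), Pnpla3 was lower by a log2 of -2.91 ± 0.51 and Per2, a clock repressor, by -1.56 ± 0.27 (other probes -0.23 with adjusted p = 0.789 and -1.34 with adjusted p = 0.0790), and each of these 3 ended for at least 4 of the arrays left out. Limma called 11 genes, 7 higher and 4 lower, with counts of 7, 2 and 4 without S2 24 h replicates 1, 2 and 4, of 5, 2 and 3 without S19 24 h replicates 1, 3 and 4, 21 in the deposited matrix and 22 in a fit of only the 2 groups. The cholesterol list was lower after serotype 2 than after serotype 19 (0 of 16 over all genes, 2 lower adjusted over the list alone, median -0.18, adjusted p = 0.0184, adjusted p = 0.542 with an estimated correlation). That call ended under median scaling (-0.22, adjusted p = 0.0941), without S2 24 h replicate 1 (-0.082, adjusted p = 0.170) and without S19 24 h replicate 4 (-0.12, adjusted p = 0.163). Acute phase genes were higher after serotype 2 as a list (0 of 31 over all genes, 14 higher adjusted over the list alone, median 0.56, adjusted p = 3.28e-13, adjusted p = 0.292 with an estimated correlation), with a median of 0.33 without S19 24 h replicate 3. Interferon-stimulated genes shifted upward as a list only (0 of 35, 0 adjusted over the list alone, median 0.37, adjusted p = 7.32e-07, adjusted p = 0.475 with an estimated correlation), and not without S2 24 h replicate 4 (0.044, adjusted p = 0.369). At 6 h limma called 0 genes between the serotypes in liver (1039 unadjusted), 0 under each other setting and 39 without S19 6 h replicate 3, and the cholesterol list did not pass (median -0.16, adjusted p = 0.271) except without S2 6 h replicate 4 (-0.32, adjusted p = 0.0216).

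Liver at 24 h was also set against 6 h within each serotype. After serotype 2, Prtn3 rose by 5.06 ± 0.76 and the clock activator gene Arntl by 2.86 ± 0.39 (detected on 3 of 4 arrays at 6 h), while Cyp2b10 fell by 4.35 ± 0.51 and Cyp7a1 fell by 4.30 ± 0.68. Limma called 2097 genes, 1173 higher and 924 lower. Under median scaling 67.5% of called genes were higher in place of 55.9%. Cholesterol genes rose in 9 of 16 members and fell in 1 (13 and 1 adjusted over the list alone, median 0.97, adjusted p = 3.84e-05, adjusted p = 0.302 with an estimated correlation). Complement and coagulation genes rose in 15 of 29 members (18 adjusted over the list alone, median 0.43, adjusted p = 1.41e-07), a list call that held with an estimated correlation (adjusted p = 0.0282). Mbl1 rose by 0.90 ± 0.13. Clock genes fell in 7 of 14 members and rose in 3 (7 and 3 adjusted over the list alone, median -0.67, adjusted p = 0.00427, adjusted p = 0.258 with an estimated correlation). Per2 fell by 2.47 ± 0.27. Fatty acid oxidation genes fell in 6 of 19 members (10 adjusted over the list alone, median -0.27, adjusted p = 0.000776, adjusted p = 0.337 with an estimated correlation). The clock median was -0.17 with no detection filter and -1.11 with the strict filter.

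After serotype 19, Nfe2 rose by 3.87 ± 0.30 from 6 to 24 h (detected on 2 of 4 arrays at 6 h) and Mvd by 3.79 ± 0.39, Cidec was at least 39.4-fold lower and Eif4ebp3 fell by 4.04 ± 0.44. Limma called 2701 genes, 1608 higher and 1093 lower, and 83.7% were higher under median scaling in place of 59.5%. Cholesterol genes rose in 10 of 16 members and fell in 1 (11 and 1 adjusted over the list alone, median 1.04, adjusted p = 5.79e-05, adjusted p = 0.534 with an estimated correlation). Fatty acid oxidation genes fell in 12 of 19 members (13 adjusted over the list alone, median -0.57, adjusted p = 2.87e-06, adjusted p = 0.492 with an estimated correlation). Under median scaling the median of all liver genes was 0.15 for serotype 19 at 24 h against sham, 0.20 for serotype 19 at 24 against 6 h and -0.12 for the interaction. Of 177 named liver values, 162 still passed under median scaling, and 135 of 174 in a fit of only the 2 groups.

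To ask whether the change in cholesterol genes differed between tissues, the change from sham in liver was set against that in lung and blood. Liver exceeded lung by a median of 0.78 for serotype 2 at 24 h (4 of 16 genes more positive in liver, adjusted p = 0.00258, adjusted p = 0.232 with an estimated correlation) and by 1.29 for serotype 19 at 24 h (5 of 16, adjusted p = 1.80e-06, adjusted p = 0.0961 with an estimated correlation). Over blood, the excess was 0.87 for serotype 19 at 24 h (6 of 16, adjusted p = 0.00700, adjusted p = 0.400 with an estimated correlation). For serotype 2 at 24 h it was 0.58 (4 more positive and 1 more negative of 16, adjusted p = 0.0352, adjusted p = 0.646 with an estimated correlation), a call that ended without liver sham replicate 2 (adjusted p = 0.150), liver S2 24 h replicate 2 (0.0509) or 3 (0.0602), blood sham replicate 1 (0.0766) or 2 (0.0616), or blood S2 24 h replicate 1 (0.0744) or 4 (0.0846). At 6 h no difference passed (liver minus lung -0.074 with adjusted p = 0.392 and 0.13 with adjusted p = 0.133, liver minus blood 0.050 with adjusted p = 0.966 and 0.23 with adjusted p = 0.412, for serotypes 2 and 19). In lung itself the list did not pass at 24 h for serotype 2 (1 of 16 higher and 1 lower, also adjusted over the list alone, median 0.31, adjusted p = 0.102) or serotype 19 (1 higher and 2 lower, also adjusted over the list alone, median 0.26, adjusted p = 0.445). Pmvk fell there in both, by 0.98 ± 0.17 and by 1.16 ± 0.17.

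The lung comparisons asked how the infected organ responded to the invasive and the lobar strain. At 24 h after serotype 2 the lung carried far more chemokine, interferon-stimulated and neutrophil transcripts than sham lung. Acod1, the enzyme that makes itaconate in activated macrophages, rose by 6.77 ± 1.13 (detected on 2 of 3 sham arrays), and the interferon-induced chemokine genes Cxcl9 and Cxcl10 rose by 6.14 ± 1.09 and 6.12 ± 1.07. Angptl7 fell by 3.52 ± 0.56 (detected on 1 of 4 infected arrays, another probe -1.53) and the gelsolin gene Gsn fell by 2.37 ± 0.29 (another probe gave -0.60, adjusted p = 0.0884). Limma called 2762 of 13399 genes, 1497 higher and 1265 lower, of which 665 at least doubled and 283 at least halved. The count was 1685 without sham replicate 2 and 1763 without S2 24 h replicate 1, and 1264 in a fit of only the 2 groups. Of the called genes 54.2% were higher, against 68.7% in the deposited matrix and 87.01% under median scaling.

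Sham replicate 3 and S2 24 h replicate 2 carried high muscle transcripts in lung, with Acta1, the skeletal muscle actin gene, at log2 15.48 and 14.02 against a median of 4.64 on the other 17 arrays. With that pair left out the lung counts at 24 h against sham were 2176 for serotype 2 and 1453 for serotype 19. The muscle list did not pass for serotype 2 at 24 h (0 of 15 genes, 0 adjusted over the list alone, median -0.86, adjusted p = 0.187). It did under median scaling (-0.66, adjusted p = 0.00858), without sham replicate 2 (-1.89, adjusted p = 0.0174) and without S2 24 h replicate 2 (-2.11, adjusted p = 0.00161), and its median was -0.070 (adjusted p = 0.857) without sham replicate 3 and -0.48 and -0.26 without S2 24 h replicates 1 and 4. For serotype 19 at 24 h it passed (0 of 15 genes, 0 adjusted over the list alone, median -0.85, adjusted p = 0.0448, adjusted p = 0.686 with an estimated correlation), but not without sham replicate 3 (-0.13, adjusted p = 0.541), S19 24 h replicate 1 (-0.79, adjusted p = 0.0553) or replicate 3 (-0.56, adjusted p = 0.106), or with the strict filter (adjusted p = 0.109). Its median was -1.74 without sham replicate 2 and -1.30 without S19 24 h replicate 2.

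Interferon-stimulated genes rose in 36 of 39 members in lung after serotype 2 at 24 h (37 adjusted over the list alone), with a median of 2.91 and an adjusted p = 1.37e-29 (adjusted p = 0.283 with an estimated correlation). Oas1g rose by 4.05 ± 0.48. Cytokine and chemokine genes rose in 27 of 35 members (29 adjusted over the list alone, median 1.55, adjusted p = 1.9e-13, adjusted p = 0.289 with an estimated correlation). Neutrophil markers rose in 17 of 19 members (18 adjusted over the list alone, median 2.46, adjusted p = 3.78e-11, adjusted p = 0.283 with an estimated correlation). Cd177 rose by 3.85 ± 0.69. T and NK cell markers rose in 14 of 24 members (18 adjusted over the list alone, median 0.76, adjusted p = 8.23e-08, adjusted p = 0.289 with an estimated correlation). Monocyte and macrophage markers rose in 11 of 25 members and fell in 2 (15 and 2 adjusted over the list alone, median 0.72, adjusted p = 0.000152, adjusted p = 0.351 with an estimated correlation). The Fc receptor gene Fcgr1 rose by 4.30 ± 0.59 (detected on 2 of 3 sham arrays), while the haemoglobin scavenger receptor gene Cd163 fell by 1.70 ± 0.32. Acute phase genes rose in 14 of 29 members and fell in 1 (15 and 1 adjusted over the list alone, median 0.68, adjusted p = 6.39e-06, adjusted p = 0.351 with an estimated correlation). Haemopexin (Hpx) rose by 2.19 ± 0.41.

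Lower in lung after serotype 2 at 24 h were drug-metabolising genes, stromal and alveolar markers and clock genes. Drug metabolism genes fell in 8 of 16 members (10 adjusted over the list alone, median -0.96, adjusted p = 0.000124, adjusted p = 0.283 with an estimated correlation). The list median was -0.058 with no detection filter. Endothelial and stromal markers fell in 8 of 27 members (8 adjusted over the list alone, median -0.33, adjusted p = 0.00417, adjusted p = 0.496 with an estimated correlation). The list median was -0.11 under median scaling and -0.52 without S2 24 h replicate 3. Alveolar epithelium markers fell in 4 of 20 members (6 lower and 1 higher adjusted over the list alone, median -0.38, adjusted p = 0.0208, adjusted p = 0.482 with an estimated correlation). Surfactant protein B (Sftpb) fell by 0.92 ± 0.17. The alveolar call ended without sham replicate 2 (adjusted p = 0.0598) and without S2 24 h replicate 2 (adjusted p = 0.0549), and its median was -0.12 under median scaling. Erythroid markers fell in 6 of 16 members (6 adjusted over the list alone, median -0.43, adjusted p = 0.00956, adjusted p = 0.290 with an estimated correlation), a call that ended without sham replicate 3 (adjusted p = 0.106). Clock genes fell in 9 of 15 members and rose in 2 (11 and 3 adjusted over the list alone, median -1.02, adjusted p = 0.000722, adjusted p = 0.283 with an estimated correlation). Fatty acid oxidation genes fell in 2 of 15 members (2 adjusted over the list alone, median -0.41, adjusted p = 0.00779, adjusted p = 0.283 with an estimated correlation), but not as a list without sham replicate 3, an array with high muscle transcripts (-0.14, adjusted p = 0.179), and by a median of -0.18 with both muscle-high arrays left out and -0.15 under median scaling.

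Lung 24 h after serotype 19 showed rises of interferon-stimulated genes beside falls of glucocorticoid-responsive genes. Spon2, which encodes a matrix protein of innate immunity, rose by 3.41 ± 0.24, and Mmp12, macrophage elastase, was at least 4.82-fold higher. The fibrinogen chain gene Fga fell by 4.16 ± 0.58 (detected on 2 of 4 infected arrays) and Fgg fell by 3.59 ± 0.42. Pdk4, which restrains glucose oxidation, fell by 4.09 ± 0.85, and Fkbp5, a glucocorticoid receptor co-chaperone, fell by 2.74 ± 0.47. Limma called 2178 genes, 1259 higher and 919 lower, of which 257 at least doubled and 215 at least halved. The count was 1232 without sham replicate 2, 873 in a fit of only the 2 groups and 1136 under median scaling, with 44.9% higher in place of 57.8%.

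Glucocorticoid-responsive genes fell in 8 of 16 members and rose in 1 in lung after serotype 19 at 24 h (10 and 1 adjusted over the list alone, median -0.99, adjusted p = 0.000143, adjusted p = 0.686 with an estimated correlation). Errfi1 fell by 1.07 ± 0.21. Fatty acid oxidation genes fell in 7 of 15 members (8 adjusted over the list alone, median -0.61, adjusted p = 0.000143, adjusted p = 0.296 with an estimated correlation). The list median was -0.21 (adjusted p = 0.0185) without sham replicate 3, the array with high muscle transcripts, and -0.34 with no detection filter. Interferon-stimulated genes rose in 14 of 39 members (19 adjusted over the list alone, median 1.21, adjusted p = 1.28e-07, adjusted p = 0.686 with an estimated correlation). The list median was 0.60 without S19 24 h replicate 2. The neutrophil list had 2 of 19 members higher (1 adjusted over the list alone) and did not pass (median 0.81, adjusted p = 0.0535). It passed without sham replicate 1 (0.83, adjusted p = 0.0104), S19 24 h replicate 3 (1.30, adjusted p = 0.000434) or replicate 4 (0.90, adjusted p = 0.0381), and in 6 other settings, and its median was 0.42 (adjusted p = 0.440) without S19 24 h replicate 2 and 0.53 without sham replicate 2. Monocyte and macrophage markers as a list did not pass (5 of 25 higher and 2 lower, 6 and 5 adjusted over the list alone, median 0.23, adjusted p = 0.566, median 0.012 to 0.49 with 1 array left out). The acute phase list did not pass and its median of 0.14 and mean of -0.04 had different signs (2 of 29 higher and 3 lower, 2 and 4 adjusted over the list alone, adjusted p = 0.851), with a median of -0.038 without S19 24 h replicate 2. The cytokine list had 2 of 35 members higher (0 adjusted over the list alone, median 0.37, adjusted p = 0.169), with -0.10 without S19 24 h replicate 2 and 0.64 (adjusted p = 0.00702) without replicate 3.

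In lung at 6 h limma called 0 genes against sham for either serotype, where 1675 genes for serotype 2 and 1089 for serotype 19 had an unadjusted p under 0.05. The serotype 2 count was 3 with an offset of 50, 3 with all arrays normalized together, 1 over all probes, 2 with a variance trend, 8 without sham replicate 1, 1 without sham replicate 2 and 1 without S2 6 h replicate 1. The serotype 19 count was 0 in every setting. Cytokine and chemokine genes shifted upward as a list, by a median of 0.58 for serotype 19 (0 of 35, 0 adjusted over the list alone, adjusted p = 3.38e-05, adjusted p = 0.578 with an estimated correlation) and 0.48 for serotype 2 (0 of 35, 0 adjusted over the list alone, adjusted p = 0.00644, adjusted p = 0.803 with an estimated correlation), the latter not without sham replicate 1 (0.35, adjusted p = 0.139). Neutrophil markers shifted upward as a list too, by a median of 0.71 for serotype 2 (0 of 19, 0 adjusted over the list alone, adjusted p = 0.0312, adjusted p = 0.803 with an estimated correlation) and 0.65 for serotype 19 (0 of 19, 0 adjusted over the list alone, adjusted p = 0.00570, adjusted p = 0.578 with an estimated correlation). The serotype 2 call ended without sham replicate 2 (0.45, adjusted p = 0.282) or 3 (0.56, adjusted p = 0.124) or S2 6 h replicate 1 (0.52, adjusted p = 0.158) or 4 (0.59, adjusted p = 0.143) and with the strict filter (adjusted p = 0.0639). That for serotype 19 ended without sham replicate 2 (0.41, adjusted p = 0.134) or S19 6 h replicate 2 (0.49, adjusted p = 0.0765), and its median was 0.42 without S19 6 h replicate 1. The abundant cytokine list member Icam1 gave 0.42 ± 0.15 for serotype 19 and 0.13 ± 0.15 for serotype 2. The muscle list shifted downward by a median of -2.18 for serotype 2 (0 of 15, 0 adjusted over the list alone, adjusted p = 2.13e-06, adjusted p = 0.455 with an estimated correlation). That shift was -0.99 (adjusted p = 0.01002) without sham replicate 3, the sham lung with the highest muscle transcripts.

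**Figure D3:**
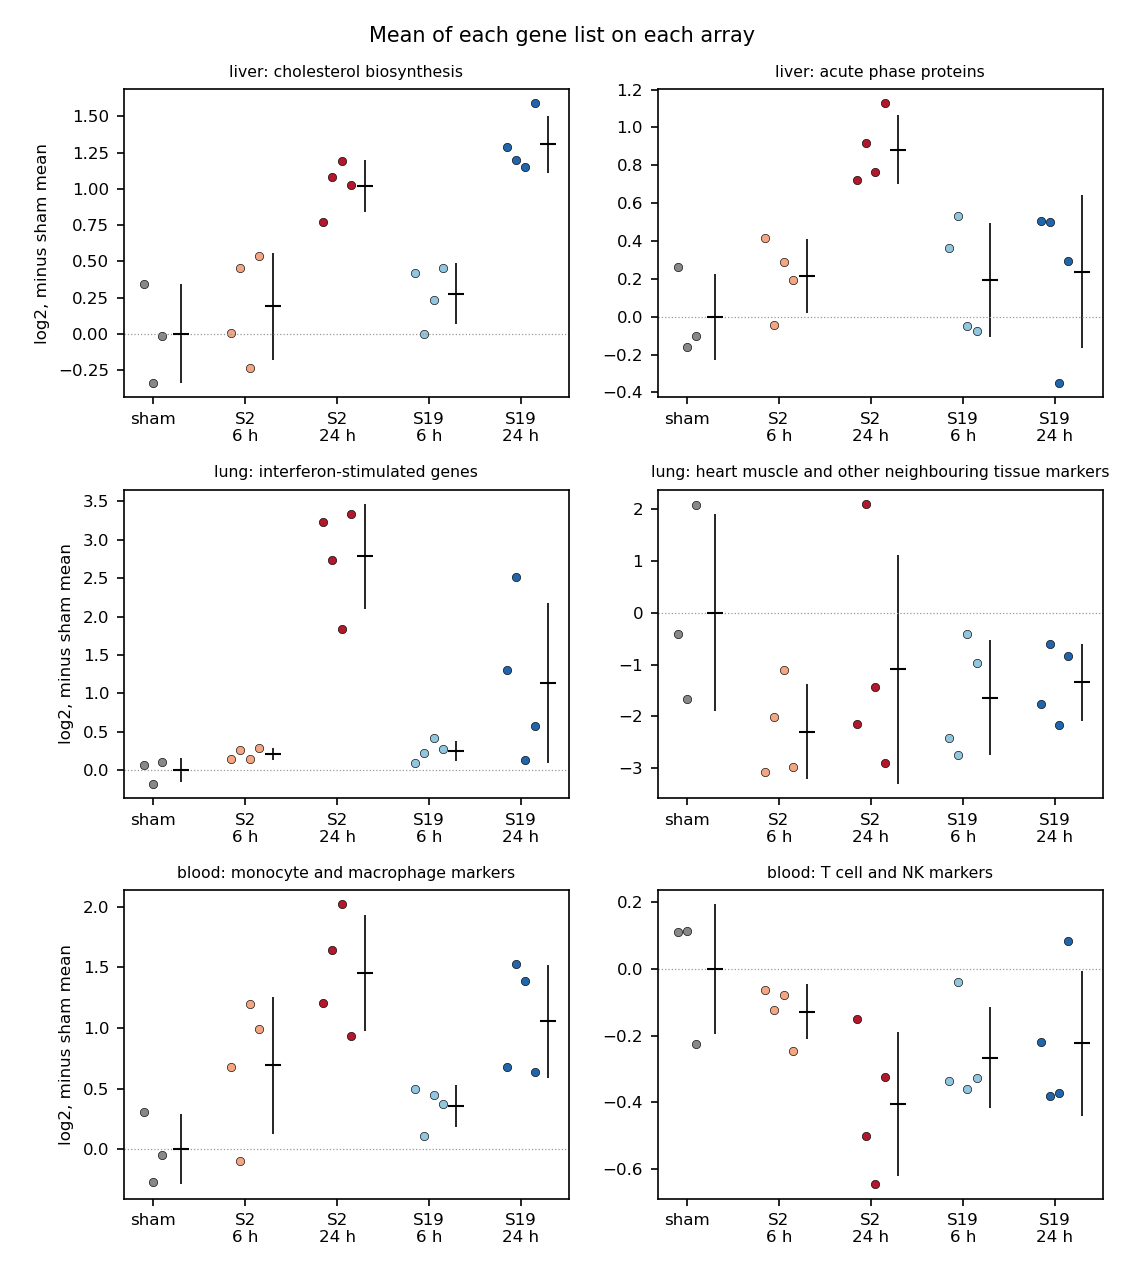
Mean log2 signal of a gene list on each array minus the sham mean (vertical axes) for liver cholesterol biosynthesis and acute phase genes, lung interferon-stimulated genes and muscle markers, and blood monocyte and T and NK cell markers, by group (horizontal axes). Dots are arrays and bars are group means with SD, and in liver all 4 arrays of each serotype at 24 h lie above the 3 sham arrays for cholesterol biosynthesis.

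Compared directly at 24 h, lung after serotype 2 held more interferon, chemokine, neutrophil and acute phase transcripts than lung after serotype 19, and less of the epithelial and stromal markers. Fga was higher by 3.10 ± 0.54 (detected on 2 of 4 serotype 19 arrays). Thbd, which encodes the anticoagulant receptor thrombomodulin, was lower by a log2 of -1.82 ± 0.21. Limma called 2540 genes, 1124 higher and 1416 lower. Counts were 1214 without S2 24 h replicate 1, 1345 without replicate 4, 1647 and 1216 without S19 24 h replicates 1 and 3, 655 in a fit of only the 2 groups and 1889 with the muscle-high arrays left out. The share higher was 44.3%, against 68.7% in the deposited matrix and 89.4% under median scaling. Interferon-stimulated genes were higher in 32 of 39 members (36 adjusted over the list alone, median 1.62, adjusted p = 2.22e-19, adjusted p = 0.406 with an estimated correlation). Cytokine genes were higher in 24 of 35 members (27 higher and 1 lower adjusted over the list alone, median 1.38, adjusted p = 3.17e-12, adjusted p = 0.406 with an estimated correlation). Neutrophil markers were higher in 11 of 19 members (14 adjusted over the list alone, median 1.44, adjusted p = 2.82e-08, adjusted p = 0.406 with an estimated correlation). Acute phase genes were higher in 15 of 29 members (17 adjusted over the list alone, median 1.15, adjusted p = 1.1e-08, adjusted p = 0.406 with an estimated correlation), with a median of 0.72 without S19 24 h replicate 3. Airway epithelium markers were lower in 7 of 19 members (9 adjusted over the list alone, median -0.82, adjusted p = 0.000354, adjusted p = 0.406 with an estimated correlation), including the club cell gene Cyp2f2 by -1.20 ± 0.22, with medians of -0.41 without S2 24 h replicate 4 and -0.45 under median scaling. Endothelial and stromal markers were lower in 12 of 27 members (16 adjusted over the list alone, median -0.56, adjusted p = 5.11e-06, adjusted p = 0.406 with an estimated correlation), with medians of -0.37 in the deposited matrix and -0.17 under median scaling. At 6 h limma called 0 genes between the serotypes (890 unadjusted), and 0 under each other setting. Cell cycle genes were then lower after serotype 2 as a list (0 of 26 over all genes, 18 lower adjusted over the list alone, median -0.48, adjusted p = 1.38e-17, adjusted p = 0.104 with an estimated correlation).

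From 6 to 24 h after serotype 2, lung Cxcl9 rose by 6.45 ± 1.01 and Cxcl10 by 5.50 ± 0.99, and the clock gene Per2 fell by 1.75 ± 0.15 while Arntl rose by 1.75 ± 0.25. Limma called 3747 genes, 1819 higher and 1928 lower, with 48.5% higher against 63.4% in the deposited matrix and 81.5% under median scaling. Clock genes fell in 9 of 15 members and rose in 2 (10 and 2 adjusted over the list alone, median -1.05, adjusted p = 0.00121, adjusted p = 0.304 with an estimated correlation). After serotype 19, Spon2 rose by 3.20 ± 0.23, Fgg fell by 3.61 ± 0.39 and Fkbp5 fell by 3.04 ± 0.43. Limma called 1980 genes, 994 higher and 986 lower, with 1191 without S19 6 h replicate 1 and 1258 without S19 24 h replicate 1, and with 50.2% higher against 37.8% in the deposited matrix and 15.6% under median scaling. Glucocorticoid-responsive genes fell in 12 of 16 members and rose in 1 (12 and 1 adjusted over the list alone, median -1.16, adjusted p = 1.44e-07, adjusted p = 0.613 with an estimated correlation). Under median scaling the median of all lung genes was 0.16 for serotype 2 at 24 h and 0.13 for serotype 19 at 6 h against sham, 0.22 between serotypes at 24 h and -0.11 at 6 h, 0.15 and -0.13 for 24 against 6 h, and 0.34 for the interaction. Of 179 named lung values 159 still passed under median scaling and 167 with the muscle-high arrays left out.

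The blood comparisons asked how circulating cells responded. Most calls ended under median scaling, where limma called 3 genes for serotype 2 and 1 for serotype 19 at 6 h against sham, and 18 and 2 at 24 h, and 8 of 167 named blood values still passed. The median change of the called genes in their direction was about as large there, at 0.86 and 0.91 for serotype 2 and 0.98 and 0.85 for serotype 19 at 6 and 24 h, against 0.88, 0.91, 0.86 and 0.90 with quantile normalization, while their residual SD was 0.65 to 0.66 against 0.27 to 0.30. In the deposited matrix 124 of the 167 passed. The detected percent of probes averaged 33.4 in sham blood (SD 4.02, n = 3), 36.2 and 35.6 for serotype 2 at 6 and 24 h, and 32.3 and 38.4 for serotype 19. Under median scaling the median of all blood genes was 0.15 and 0.10 for serotype 2 and -0.21 and 0.20 for serotype 19 at 6 and 24 h against sham, 0.50 between serotypes at 6 h, 0.51 for serotype 19 at 24 against 6 h and -0.54 for the interaction. In the deposited matrix the last 3 were 0.16, 0.17 and -0.15.

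In blood 6 h after serotype 2, neutrophil and monocyte markers were higher than in sham. Ngp, a granule gene of maturing neutrophils, rose by 2.53 ± 0.55 (detected on 1 of 3 sham arrays) and Eef2, a translation factor gene, by 2.76 ± 0.24. Ms4a4b, a T cell surface gene, fell by 2.26 ± 0.30 (another probe gave -0.27, adjusted p = 0.489). Fyn, a T cell kinase gene, rose by 2.69 ± 0.33 (detected on 2 of 3 sham arrays), and another Fyn probe gave -0.09. Limma called 2069 of 11181 genes, 919 higher and 1150 lower, 951 in the deposited matrix (75.4% higher in place of 44.4%). Neutrophil markers rose in 6 of 21 members (9 adjusted over the list alone, median 0.98, adjusted p = 2.58e-05, adjusted p = 0.768 with an estimated correlation). Monocyte markers rose in 4 of 19 members (6 adjusted over the list alone, median 0.52, adjusted p = 0.0047, adjusted p = 0.768 with an estimated correlation). That median was 0.25 without sham replicate 2 or S2 6 h replicate 3 and 0.85 without S2 6 h replicate 2. The cholesterol list did not pass in blood (1 of 14 higher and 1 lower, also adjusted over the list alone, median 0.13, adjusted p = 0.585).

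At 24 h after serotype 2, blood Ms4a6d, a macrophage membrane gene, was higher by 3.60 ± 0.61, the interferon-induced Ifi207 by 3.29 ± 0.41 and Saa3, a serum amyloid gene, by 3.08 ± 0.53, the last pair detected on 1 of 3 sham arrays. Socs2, a growth hormone feedback gene, fell by 2.88 ± 0.32 and beta globin (Hbb-b2), a target of the globin clearing, fell by 1.98 ± 0.35. Limma called 2544 genes, 1213 higher and 1331 lower, and 1382 in the deposited matrix (69.3% higher in place of 47.7%). Interferon-stimulated genes rose in 20 of 37 members (20 higher and 1 lower adjusted over the list alone, median 1.12, adjusted p = 9.5e-09, adjusted p = 0.350 with an estimated correlation). The immunoproteasome subunit Psmb8 rose by 2.76 ± 0.23. That median was 0.71 without S2 24 h replicate 3. Monocyte markers rose in 11 of 19 members (15 adjusted over the list alone, median 1.501, adjusted p = 1.29e-08, adjusted p = 0.350 with an estimated correlation). Fcgr1 rose by 3.002 ± 0.49 (detected on 2 of 3 sham arrays). Neutrophil markers rose in 8 of 21 members (12 adjusted over the list alone, median 1.26, adjusted p = 6.33e-05, adjusted p = 0.475 with an estimated correlation). T and NK cell markers fell in 10 of 25 members (10 lower and 1 higher adjusted over the list alone, median -0.44, adjusted p = 0.0280, adjusted p = 0.475 with an estimated correlation). The T cell receptor chain gene Cd3g fell by 1.20 ± 0.25. That call ended without sham replicate 1 (adjusted p = 0.0580), sham replicate 2 (0.0659) or S2 24 h replicate 3 (0.0723), and under median scaling (median -0.20, adjusted p = 0.0861). Erythroid markers did not pass as a list (1 of 22 higher and 6 lower, 1 and 7 adjusted over the list alone, median -0.46, adjusted p = 0.0700). They did in the deposited matrix (-0.40, adjusted p = 0.00516), under median scaling (-0.21, adjusted p = 0.00272) and without sham replicate 1 (-0.53, adjusted p = 0.0213) or 2 (-0.51, adjusted p = 0.0378) or S2 24 h replicate 4 (-0.53, adjusted p = 0.0352), and the median was -0.22 without sham replicate 3. The cholesterol list did not pass (2 of 14 higher and 1 lower, also adjusted over the list alone, median 0.19, adjusted p = 0.396).

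In blood after serotype 19, Eef2 rose by 2.91 ± 0.24 and the thrombospondin gene Thbs1, carried by platelets, by 2.00 ± 0.21 at 6 h (detected on 2 of 3 sham arrays), and the NK receptor gene Klra8 fell by 1.61 ± 0.26. Limma called 1680 genes at 6 h, 712 higher and 968 lower, 518 in the deposited matrix and 891 in a fit of only the 2 groups. At 24 h the eosinophil ribonuclease gene Ear3 was higher by 2.27 ± 0.29, and Socs2 fell by 2.74 ± 0.32. The 24 h count was 1709, 780 higher and 929 lower, with 950 without sham replicate 2, 1000 without sham replicate 3, 1039 without S19 24 h replicate 2, 1074 with the detected share as a covariate and 774 in the deposited matrix (76.2% higher in place of 45.6%). B cell markers rose in 6 of 17 members (8 adjusted over the list alone, median 0.54, adjusted p = 7.68e-05, adjusted p = 0.413 with an estimated correlation). Monocyte markers rose in 9 of 19 members (10 adjusted over the list alone, median 0.79, adjusted p = 3.36e-06, adjusted p = 0.413 with an estimated correlation). Interferon-stimulated genes rose in 8 of 37 members (8 adjusted over the list alone, median 0.30, adjusted p = 0.00388, adjusted p = 0.590 with an estimated correlation). Psmb8 rose by 2.20 ± 0.23, and the list median was 0.17 without S19 24 h replicate 3. The cholesterol list did not pass at 6 h (median -0.10, adjusted p = 0.908) or 24 h (median 0.26, adjusted p = 0.161), with 1 of 14 members higher and 1 lower each time, also adjusted over the list alone.

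Directly between serotypes at 24 h, blood Cxcl9 was higher after serotype 2 by 2.51 ± 0.37 (detected on 3 of 4 serotype 19 arrays), and the B cell genes Bank1 and Cr2 were lower by a log2 of -1.91 ± 0.30 and -1.54 ± 0.20, with Cr2 detected on 1 of 4 serotype 2 arrays. Limma called 51 genes, 4 higher and 47 lower. That count was 13, 7 and 22 without S2 24 h replicates 1 to 3, 19, 16, 20 and 12 without S19 24 h replicates 1 to 4, 11 in the deposited matrix, 0 under median scaling, 17 with all arrays normalized together and 16 with no filter. B cell markers were lower in 2 of 17 members (8 adjusted over the list alone, median -0.54, adjusted p = 7.71e-12, adjusted p = 0.559 with an estimated correlation). Interferon-stimulated genes were higher in 1 of 37 members (13 adjusted over the list alone, median 0.50, adjusted p = 5.17e-10, adjusted p = 0.559 with an estimated correlation), with a median of 0.27 without S2 24 h replicate 3. At 6 h limma called 0 genes between the serotypes (1018 unadjusted, 0 under each other setting), with 10 without S2 6 h replicate 2 and 8 without S19 6 h replicate 4.

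From 6 to 24 h after serotype 2, blood Cxcl9 rose by 3.52 ± 0.37 (detected on 1 of 4 arrays at 6 h) and the macrophage gene Aif1 by 2.91 ± 0.41 (other probes 2.77 with adjusted p = 0.000687 and 0.045 with adjusted p = 0.958). The lymphocyte chemokine receptor genes Cxcr6 and Cxcr3 fell by 2.46 ± 0.41 and by 1.98 ± 0.32, with Cxcr6 detected on 2 of 4 arrays at 24 h. Limma called 418 genes, 228 higher and 190 lower, with 132 without S2 6 h replicate 4, 164 and 120 without S2 24 h replicates 2 and 3, 106 in the deposited matrix, 1 under median scaling and 273 with all arrays normalized together. Interferon-stimulated genes rose in 15 of 37 members (20 adjusted over the list alone, median 0.66, adjusted p = 1.48e-13, adjusted p = 0.204 with an estimated correlation), with a median of 0.43 without S2 24 h replicate 3. After serotype 19 limma called 524 genes, 251 higher and 273 lower, including the macrophage gene Adgre1, up by 1.83 ± 0.34 (another probe 0.50, adjusted p = 0.164), and Thbs1, down by 1.18 ± 0.20. That count was 71 and 335 without S19 6 h replicates 3 and 4, 68, 38 and 140 without S19 24 h replicates 2 to 4, 100 in the deposited matrix, 0 under median scaling, 215 with all arrays normalized together, 348 in a fit of only the 2 groups and 1 with the detected share as a covariate.

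Whether the time course differed between serotypes was tested as an interaction, the change from 6 to 24 h after serotype 2 minus that after serotype 19. In lung 1186 genes passed, 516 positive and 670 negative, and in liver 3 and in blood 66 (1 positive and 65 negative). The genes named here were chosen after their values were seen. Cxcl9 had an interaction of 5.53 (adjusted p = 0.0258) and Thbd of -2.09 (adjusted p = 0.00237) in lung. In liver the 3 genes were Chac1 at 3.26 (adjusted p = 0.0192), the ceramide kinase-like gene Cerkl at 1.29 (adjusted p = 0.0237) and Rbm33, an RNA-binding protein gene, at 1.17 (adjusted p = 0.0237). In blood Cxcl9 had 2.61 (adjusted p = 0.0287) and Cxcr6 -3.10 (adjusted p = 0.0251). Interferon-stimulated genes were positive in 10 of 39 members in lung (29 adjusted over the list alone, median 1.63, adjusted p = 7.06e-14, adjusted p = 0.447 with an estimated correlation) and acute phase genes in 11 of 29 (19 adjusted over the list alone, median 1.60, adjusted p = 1.86e-09, adjusted p = 0.447 with an estimated correlation).

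The lung interaction count was 726 and 653 without S2 6 h replicates 1 and 2, 548, 725, 2313 and 670 without S2 24 h replicates 1 to 4, 634 and 789 without S19 6 h replicates 1 and 2, and 743, 1950 and 521 without S19 24 h replicates 1 to 3. It was 1909 in the deposited matrix, 2930 under median scaling and 730 with the muscle-high arrays left out, and 43.5% of its genes were positive against 72.2% and 92.2% under the first pair. The liver count was 37 without S19 6 h replicate 3, 6 without S19 6 h replicate 4 or S2 6 h replicate 3, 1 without S2 6 h replicate 1, S19 6 h replicate 1 or 2 or S19 24 h replicate 1 or 2, 0 without S2 6 h replicate 2, S2 24 h replicate 2 or 3 or S19 24 h replicate 4, 5 under median scaling or the strict filter and 6 with a variance trend. The blood count was 4, 225, 5 and 3 without S2 6 h replicates 1 to 4, 7, 8 and 36 without S2 24 h replicates 1, 2 and 4, 133, 7, 10 and 32 without S19 6 h replicates 1 to 4, and 32, 10 and 4 without S19 24 h replicates 2 to 4. It was 0 under median scaling, 4 with all arrays normalized together, 8 with no filter and 1 with the detected share as a covariate.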

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

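Of the tests below, the splits of arrays and the median scaling test in blood were set out before the results were seen, and the others (a sham array, time of day, food intake, both muscle tests and the detected share) were chosen only afterwards.

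Genes of cholesterol biosynthesis were higher in liver 24 h after both serotypes, a list call that ended with an estimated correlation (adjusted p = 0.208 and 0.140). A single unusual sham array is argued against, since without sham replicate 2 the medians were still 0.81 for serotype 2 and 1.05 for serotype 19. Lower food intake, which would raise fatty acid oxidation genes as in a fasted liver, cannot be told apart from infection, since members of that list that were higher minus those lower came to -3 and -3 but the list did not pass, went both ways (1 higher and 2 lower, and 2 and 3, under median scaling, against 1 and 5, and 1 and 7, in the deposited matrix) and had a median of 0.034 (adjusted p = 0.0390) for serotype 19 under median scaling. Nor can time of day, since sham livers were marked 6 h only and 71.4% and 42.9% of clock genes passed between 24 and 6 h, against 18.1% and 23.3% of all genes. A remote response of the liver stays open as a hypothesis beside both.

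In lung, muscle transcripts were highest on 2 arrays. Muscle tissue carried over into those samples was not tested independently and stays open. For 11 of 11 muscle genes sham replicate 3 and S2 24 h replicate 2 ranked first and second of 19, which is how these arrays were noticed. A change after infection stays open too, since the list median at 6 h was -2.18 for serotype 2 (adjusted p = 0.455 with an estimated correlation) and -1.29 for serotype 19 (adjusted p = 0.578 with an estimated correlation) with all arrays. Without sham replicate 3 it was -0.99 (adjusted p = 0.01002) and -0.58 (adjusted p = 0.115), and with both muscle-high arrays left out the same medians had adjusted p = 0.000226 and 0.0228. For serotype 19 it was also -2.18 without sham replicate 2 and -0.71 without S19 6 h replicate 2.

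Nearly all genes called in blood against sham at 6 h lost their call under median scaling. The median change of the called genes in their direction was 0.86 (from 0.88) for serotype 2 and 0.98 (from 0.86) for serotype 19. They were picked under quantile normalization, so its part stays open. The calls ended while the residual SD rose from 0.28 to 0.66 and from 0.27 to 0.66. With the detected share as a covariate 1916 and 1859 genes were called at 6 h, where it was near sham. It ended most serotype 19 calls at 24 against 6 h, so this share stays open. Changes in the cell mix and unequal globin clearing, which may bear on it, were not tested and stay open.

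Other splits of the same arrays were counted for every comparison, with the real split included. Chance could not be excluded where 9 of 35 splits gave as many genes (liver, serotype 2 at 6 h against sham, real 1, highest other 8) or 8 of 35 (liver, serotype 19 at 6 h, real 2, highest other 348, which points to a structure among these arrays). In lung 2 of 35 splits gave as many for serotype 2 at 24 h against sham (real 2762, highest other 3053) and between serotypes at 24 h (real 2540, highest other 2851), a share that does not by itself exclude chance. The higher split put S2 24 h replicate 3 with the 3 sham arrays, or exchanged it for S19 24 h replicate 2, so it kept the other 3 serotype 2 arrays together, and without replicate 3 the counts were 3492 and 3401. A count of 0 is met by every split (35 of 35), so the splits say nothing on chance there, and the highest others were 4 in liver, 1 in lung and 99 in blood between serotypes at 6 h, and 0 in lung against sham at 6 h for each serotype. In other comparisons 1 of 35 splits, the real one, gave as many, the lowest share possible, unadjusted. In liver the real and highest other counts were 1699 and 337 (serotype 2) and 1667 and 177 (serotype 19) at 24 h against sham, 11 and 0 between serotypes at 24 h, and 2097 and 0, and 2701 and 2, at 24 against 6 h. In lung they were 2178 and 676 for serotype 19 at 24 h, and 3747 and 1, and 1980 and 4, at 24 against 6 h. In blood they were 2069 and 1342 (serotype 2) and 1680 and 842 (serotype 19) at 6 h, 2544 and 1320, and 1709 and 671, at 24 h, 51 and 0 between serotypes, and 418 and 36, and 524 and 96, at 24 against 6 h. With serotype shuffled within each time, 2 of 100 draws gave as many interaction genes in liver (real 3, highest other 59, pointing to structure). In lung it was 1 (1186 and 819) and in blood 1 (66 and 46). Shuffling removes all serotype effects, so it cannot test interaction alone.

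Single arrays stood apart in 7 of 182 groups of 4 tested (3.85%), where chance does so in about 1 in 20 groups, by the gap to the nearest array over the group's range. The gap was 0.925 for clock genes and 0.925 for drug metabolism genes in liver S2 24 h replicate 4 (low), 0.846 for sterol uptake and feedback genes in liver S19 24 h replicate 2 (low), 0.846 for endothelial and stromal markers in lung S2 24 h replicate 3 (high) and 0.857 for fatty acid oxidation in lung S2 24 h replicate 2 (high). It was 0.898 for T and NK cell markers in blood S19 6 h replicate 2 (high) and 0.862 for Acod1 in lung S2 24 h replicate 3 (low). Interaction genes were 3 in liver, 1186 in lung and 66 in blood. Cholesterol genes changed more in liver than in lung by 0.78 and 1.29 and than in blood by 0.58 and 0.87 at 24 h (serotypes 2 and 19). With an estimated correlation none passed (adjusted p = 0.232 and 0.0961 for lung, 0.646 and 0.400 for blood), and the serotype 2 difference from blood also ended for 7 of 14 arrays left out. Probes without a gene symbol, not used in the comparisons, passed limma against sham in 339 and 311 cases in liver and 448 and 627 in lung at 24 h (serotypes 2 and 19), and in blood in 594 and 467 at 6 h and 568 and 510 at 24 h.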

How the results depend on the processing

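Of these settings, leaving out the muscle-high lung arrays and the detected share or muscle covariates were chosen after the data were seen, and the rest were planned. Replicate numbers were not taken to pair the samples, since not every pair of same-number arrays correlated over 0.1. Their median correlation was 0.008 within liver, -0.012 within lung and 0.057 within blood, and 0.050 between liver and lung (7 of 19 pairs over 0.1, against -0.017 and 5 of 54 for different numbers). No slide block was run. Values follow the order serotype 2 then 19 unless named, and for each change the cause was not tested except where fewer genes, probes or arrays or a fold requirement made it. Of the counts 365 stayed within 1.5 times and 184 moved further. Of the gene list values 1851 kept direction and side of the threshold, 183 lost their call, 39 gained one and 14 turned, and of the named gene values 8004, 1020, 0 and 15 did so. All counts between serotypes at 6 h were 0 in every setting that kept all arrays. The share of probes over background limits what could be called.

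With an offset of 50 the 6 h liver counts against sham were 0 and 56 and lung serotype 2 had 3. In the deposited matrix they were 22 and 82 in liver, 21 between serotypes at 24 h in liver, 1909 for the lung interaction, and in blood 951 and 518 at 6 h, 1382 and 774 at 24 h, 11 between serotypes at 24 h and 106 and 100 for 24 against 6 h, and the liver acute phase median for serotype 19 at 24 h was -0.016. Median scaling gave 4 for liver serotype 2 at 6 h, 1072 at 24 h, 5 for the liver interaction, 1136 for lung serotype 19 at 24 h, 2930 for the lung interaction, and in blood 3 and 1 at 6 h, 18 and 2 at 24 h, 0 between serotypes at 24 h, 1 and 0 for 24 against 6 h and 0 for the interaction. It also gave medians for serotype 19 of 0.0012 (clock) and 0.034 (fatty acid oxidation) in liver at 24 h, -0.020 (platelet markers, blood, 6 h) and 0.11 (T and NK markers, blood, 24 h), and -0.22 for liver cholesterol between serotypes at 24 h. All arrays normalized together gave 4 (liver) and 3 (lung) for serotype 2 at 6 h, and in blood 17 between serotypes at 24 h, 273 and 215 for 24 against 6 h and 4 for the interaction. With no filter blood had 16 between serotypes at 24 h and 8 for the interaction, and the lung acute phase median for serotype 19 at 24 h was -0.013, or -0.060 with the strict filter, which gave 9 and 20 in liver at 6 h and 5 for the liver interaction. A variance trend gave 9 and 31 in liver at 6 h, 6 for the liver interaction and 2 for lung serotype 2 at 6 h.

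Over all probes the counts were 2 and 8 in liver at 6 h, 2619 for liver serotype 2 at 24 h, 1 for lung serotype 2 at 6 h, 4510 and 4513 in lung at 24 h, 4244 between serotypes, 6152 and 3397 for 24 against 6 h, 1822 for the lung interaction, and in blood 3738 and 3115 at 6 h, 4347 and 3004 at 24 h, 151 between serotypes, 638 and 810 for 24 against 6 h and 145 for the interaction. A fit of only the 2 groups gave 0 for liver serotype 19 at 6 h, 677 for serotype 2 at 24 h, 22 between serotypes at 24 h, 1264 and 873 in lung at 24 h and 655 between serotypes, and in blood 891 (serotype 19, 6 h), 149 (between serotypes, 24 h) and 348 (serotype 19, 24 against 6 h). With a doubling or halving required there were 431 and 377 in liver at 24 h, 7 between serotypes, 437 and 591 for 24 against 6 h, 948 and 472 in lung at 24 h, 572 between serotypes, 1065 and 307 for 24 against 6 h, 650 for the lung interaction, and in blood 757 and 561 at 6 h, 1026 and 637 at 24 h and 205 and 165 for 24 against 6 h. Without the muscle-high arrays the lung interaction had 730. With the detected share as a covariate blood serotype 19 had 1074 at 24 h and 1 for 24 against 6 h, and the interaction 1. With the replicate number as a block for pairing, liver had 10 and 26 at 6 h and the serotype 19 cholesterol median at 6 h was 0.17 (adjusted p = 0.148).

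With an estimated correlation the liver cholesterol medians of 0.90 and 1.38 (24 h), 0.30 (serotype 19, 6 h), -0.18 (between serotypes, 24 h), 0.97 and 1.04 (24 against 6 h) and the 24 h tissue differences of 0.78 and 1.29 (lung) and 0.58 and 0.87 (blood) no longer passed. Of 99 other probes of named values past the threshold, 84 had the same sign, of which 51 passed and 33 did not, among them Gsn (-0.60, lung), Cdkn1a (-1.17), Snx10 (0.63) and Per2 (-0.23, between serotypes) in liver and Ms4a4b (-0.27, blood). Of the others 15 had the opposite sign and 0 passed, namely Lss (-0.053 at 24 h, -0.27 for 24 against 6 h) and Hsd17b7 (0.016) in liver for serotype 19, and in blood Fyn (-0.090, serotype 2), Hnrnpk (-0.10 and -0.44 for serotype 2, -0.18 and -0.60 for 19), Golga2 (0.63 and 0.70, 0.30 and 0.70), and for 19 Rab27b (-0.17), Cers4 (0.11) and Cd200 (0.070).

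With each array left out in turn, liver counts were 0 to 650 and 0 to 1267 at 6 h, 892 to 1935 and 903 to 1700 at 24 h, 0 to 39 and 2 to 16 between serotypes at 6 and 24 h and 0 to 37 for the interaction. Lung counts were 0 to 8 (serotype 2, 6 h), 1685 to 3492 and 1232 to 2171 (24 h), 1214 to 3401 (between serotypes, 24 h), 1191 to 1815 (serotype 19, 24 against 6 h) and 521 to 2313 (interaction). Blood counts were 950 to 1681 (serotype 19, 24 h), 0 to 10 and 7 to 51 (between serotypes), 120 to 564 and 38 to 711 (24 against 6 h) and 3 to 225 (interaction). Liver cholesterol medians were -0.10 to 0.34 and 0.055 to 0.38 at 6 h, and -0.32 to -0.052 and -0.23 to -0.082 between serotypes. Other medians were -0.18 to 0.0088 (liver fatty acid oxidation, serotype 2) and, for serotype 19 at 24 h, -0.015 to 0.14 (liver acute phase), -0.038 to 0.32 (lung acute phase) and -0.10 to 0.64 (lung cytokines). Tissue differences were -0.15 to 0.13 and -0.040 to 0.30 (liver minus lung, 6 h), and for liver minus blood -0.16 to 0.20 and 0.13 to 0.55 (6 h) and 0.49 to 0.72 (serotype 2, 24 h).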

Other observations

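Lung 24 h after serotype 2 also differed from 6 h in stress, proliferation and B cell genes. Oxidative and heat stress genes fell in 12 of 23 members and rose in 1 (15 and 3 adjusted over the list alone, median -1.11, adjusted p = 0.00071, adjusted p = 0.304 with an estimated correlation). The glutathione synthesis gene Gclc fell by 2.44 ± 0.34. Cell cycle genes rose in 12 of 26 members (13 adjusted over the list alone, median 0.45, adjusted p = 1.51e-05, adjusted p = 0.304 with an estimated correlation). B cell markers rose in 12 of 17 members and fell in 1 (12 and 1 adjusted over the list alone, median 0.97, adjusted p = 1.52e-05, adjusted p = 0.304 with an estimated correlation).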
